A study of Homo sapiens with 8 samples.

How the data were processed

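Polyadenylated RNA of 2 human fibroblast lines, called line 1 and line 2, was sequenced after transfection with a small interfering RNA (siRNA) against SUPT4H1 or with a non-targeting control siRNA. Per the labels, the cells grew in DMEM with 10% FBS, the siRNAs were delivered with Lipofectamine RNAiMAX, and the libraries followed Illumina's protocol for polyA RNA. The 8 samples hold 2 replicate treatments of each siRNA in each line, and the series design groups them by siRNA, 4 against 4. Nothing in the labels says that the replicates came from separate cultures grown apart, so the p-values measure only the spread between these samples, which may be technical. With 2 lines, no statement about fibroblasts in general was tested.

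The authors deposited FPKM values (fragments scaled by transcript length and by the number of mapped fragments) with lower and upper interval bounds and a status for each gene. The deposited tables have 27032 rows per sample, with hg19 coordinates per the submitters' processing notes. The aligner, the quantification tool, its version and the gene annotation are not given in the sources used here, nor is any use of strand, so overlapping antisense genes cannot be separated. FPKM are relative values: a rise in the share of a few abundant transcripts lowers all others. FPKM summed to between 288293 and 305680 per sample, and 11308 to 11446 rows per sample reached an FPKM of 1. The 10 most abundant rows held 8.5 to 8.59% of the FPKM sum in the control samples and 9.58 to 10.96% in the SUPT4H1 siRNA samples. COL1A1, COL1A2 and FN1 have the status HIDATA and are listed at 0 in all control samples, although fibroblasts make much of each, so these zeros are failed estimates, and they also change the shares of the top rows.

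The number of fragments is not given. Rows whose deposited interval had the width that 1, 2 or 3 fragments would give, within a tolerance of 0.005, were used to compare depths. Relative to the first control library of line 1, the depth was 1.03 in the other control library of line 1, 0.98 and 0.82 in the SUPT4H1 siRNA libraries of line 1, 0.863 and 1.127 in the control libraries of line 2, and 0.91 and 0.863 in the SUPT4H1 siRNA libraries of line 2. The median half-width of the deposited intervals was 14.75 to 17.41% of the value at 1 to 2 FPKM, 8.11 to 9.22% at 2 to 10 FPKM, 5.09 to 5.64% at 10 to 100 FPKM and 3.44 to 3.7% from 100 FPKM upwards, so abundant transcripts were measured more precisely. These intervals cover counting error and not the spread between cultures. No pair of samples had the same value in more than 1 of the genes compared. The SD of the log2 ratio across genes was 0.105 to 0.116 between replicates, 0.228 to 0.273 between the siRNAs within a line, and 0.41 or more between the lines. The first principal component held 77.1% of the variance and separated the lines, and the next held 16.2% and separated the siRNAs.

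Genes on the Y chromosome, XIST, TSIX and very short transcripts, with names such as MIR, SNOR, SCARNA, RNU and RN7S, were left out. The remaining rows of one symbol were summed, which gave 23129 symbols. Of these, 19835 match current or older symbols of the reference names used here. Reference data of GRCh38, with GENCODE transcripts, served only for names, transcript length and GC content. A gene was tested where its mean FPKM was at least 1 and its status was OK in every sample, which left 11423 genes. The status rule left out 12 genes of mean FPKM 1 or more, COL1A1, COL1A2 and FN1 among them. Several rows were summed for 129 of the genes tested, and values of near-identical copies such as HSPA1A and HSPA1B are uncertain.

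The test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with moderated variances that follow a mean-variance trend, 2-sided, with Benjamini-Hochberg adjustment over the 11423 genes and a threshold of 0.05. A log2 change on this scale understates the change of genes of low FPKM. The comparison of 4 against 4 had no term for the line, as the series design groups the samples. Responses of each line and the difference between them came from a fit of 4 group means, which has 4 residual degrees of freedom. Gene lists were tested with camera in limma, which compares a list with all other genes, with a preset correlation of 0.01 between members and beside it with a correlation estimated from the data, over the 19 of 25 lists that have at least 5 tested members. Named single values were tested with an exact permutation test, 2-sided, over the 70 arrangements of the labels, and for the gene span also over the 36 arrangements within the lines. Depths, names and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

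The samples of 1 line share their cells, so the line pairs the groups. Deviations of control and SUPT4H1 siRNA samples of the same line from their group means correlated at 0.876 to 0.893 across genes. A fit with the line as a replicate block therefore stands beside the results it changes. Within a line, the differences between replicates 1 and 2 of both siRNAs correlated at 0.103 in line 1 and 0.052 in line 2, and a fit with line and replicate number as block is among the alternatives.

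The design, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule takes SUPT4H1 and SUPT5H, the 12 largest rises and the 12 largest falls among genes past the threshold whose SUPT4H1 siRNA samples lie on the same side of both control samples in each line, the 3 largest changes past the threshold in each list (or the 2 most abundant members where none passed), the 4 genes per direction with the lowest p for a difference between the lines, and HTT. Other genes named from the lists were chosen after their values were seen. The lists are transcription elongation factors, RNA polymerase II subunits, repeat expansion disease genes, p53 targets, immediate early genes, interferon response, NF-kB and inflammatory genes, collagens and extracellular matrix, contractile and TGF-beta target genes, mitotic cell cycle, DNA replication and S phase, cholesterol synthesis, integrated stress and unfolded protein response, heat shock proteins, cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation, histone genes, mRNA decay and splicing factors, dermal fibroblast markers, and markers of keratinocytes, melanocytes, endothelial cells, immune cells, smooth muscle and pericytes, and neurons and glia. The alternatives were another pseudocount, other filters on FPKM, status and repeated symbols, scaling by median ratios, a fit without the trend, array weights, the replicate blocks, each sample left out in turn, an estimated correlation for the lists, other limits of gene span, and, added after the data were seen, a correction for GC content and transcript length, the line block together with an estimated correlation, an estimated correlation for the differences between the lines, and the list of elongation factors without SUPT4H1. Array weights stopped before full convergence, so that alternative is approximate.

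The steps were tested on simulated data in which 200 of the 11423 genes were changed. The 4 against 4 test recovered 43.3% of genes changed by 0.3 on the log2 scale, 76.1% at 0.6 and 93.9% at 1, with 0 false calls among 142. With the line as block it recovered 89.6, 98.5 and 100% at these sizes, with 17 false calls among 209. The test of the difference between the lines recovered 40.3, 82.1 and 98.5%, with 2 false calls among 149, and the test in line 2 recovered 61.2, 95.5 and 98.5%, with 6 false among 176. Each setting was drawn a single time with independent normal noise. For the 4 against 4 tests the change was the same in both lines. These rates therefore need not hold for the real data.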

Results

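Gene expression was measured by RNA sequencing in 2 human fibroblast lines after treatment with an siRNA against SUPT4H1 or a non-targeting siRNA. SUPT4H1 encodes SPT4, which with SPT5, the product of SUPT5H, forms DSIF, a factor that travels with RNA polymerase II and sets its pausing and elongation. Each line had 2 control and 2 SUPT4H1 siRNA samples, so that 4 samples stood against 4. Values are FPKM as the authors deposited them, given as mean ± SD over n = 4 per group unless stated otherwise, and 11423 genes were tested. Adjusted p-values are from limma.

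SUPT4H1 mRNA fell in both lines. The gene, at 17:56422536-56429599 in hg19, stood at 25.61 and 25.59 FPKM in the control samples of line 1 and at 26.18 and 28.31 in those of line 2, against 1.37 and 1.43 FPKM after SUPT4H1 siRNA in line 1 and 1.69 and 1.74 in line 2. The mean fell from 26.4 ± 1.29 to 1.56 ± 0.19 FPKM, a log2 change of -3.42 (SE 0.06, adjusted p = 2.2e-07), which leaves 5.46% of the control level in line 1 and 6.3% in line 2. An exact permutation test gave p = 0.0286, the smallest the 70 arrangements allow. SUPT5H, the partner gene at 19:39936186-39967308, stood at 22.6 ± 0.28 and 24.0 ± 1.53 FPKM, a log2 difference of 0.08 with adjusted p = 0.394 over both lines, while in line 2 alone the difference of 0.15 passed the test (adjusted p = 0.00408). The difference between the lines in SUPT5H did not pass (adjusted p = 0.104).

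Across both lines, TNC, PTX3, COL12A1 and CEMIP were among the 12 largest falls, and SERPINB2 had the largest rise. TNC, which encodes the matrix glycoprotein tenascin C (9:117781854-117880536), fell from 199.3 ± 35.7 to 79.4 ± 7.16 FPKM, a log2 change of -1.30 (SE 0.13, adjusted p = 0.00277). PTX3, a secreted pattern recognition protein of innate immunity (3:157154580-157161417), fell from 465.9 ± 41.7 to 197.4 ± 9.46 FPKM, a log2 change of -1.23 (SE 0.08, adjusted p = 7.85e-04), and COL12A1, a fibril-associated collagen (6:75794042-75915623), fell from 320.1 ± 29.1 to 160.3 ± 7.34 FPKM, a log2 change of -0.99 (adjusted p = 0.0014). CEMIP, which takes part in hyaluronan breakdown, fell from 72.8 ± 12.8 to 29.9 ± 4.08 FPKM (adjusted p = 0.00509). SERPINB2, an inhibitor of plasminogen activators (18:61554939-61571124), rose from 1.33 ± 0.58 to 12 ± 7.39 FPKM, a log2 change of 2.32 (SE 0.43, adjusted p = 0.0245). The call of SERPINB2 was lost without any 1 of the 4 control samples or of the 2 SUPT4H1 siRNA samples of line 2, with adjusted p up to 0.076. These fits have no term for the line. With all samples and the line as replicate block, SERPINB2 passed (adjusted p = 1.02e-05).

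Among the other large rises, PRELP, a small leucine-rich proteoglycan of the matrix (1:203444883-203460479), went from 20.9 ± 0.71 to 43.4 ± 3.31 FPKM (log2 change 1.02, adjusted p = 6.01e-04). GNG11, a G protein gamma subunit, went from 40.8 ± 3.11 to 82.5 ± 9.60 FPKM (log2 change 0.99, adjusted p = 0.00219). SDPR, a component of caveolae also called cavin 2, rose by 1.49 on the log2 scale, and TFPI2, a serine protease inhibitor, rose by 1.21. LOC101927740, CLCA2, C1QTNF1, LRRC17, PALMD, SLC16A4 and TNFRSF10C complete the 12 largest rises, with log2 changes of 0.89 to 1.61 (1.55 in place of 0.95 for the gene PALMD with a pseudocount of 0.1). The remaining large falls included 3 metallothioneins, small metal-binding proteins: MT1E fell from 27.4 ± 0.19 to 13.9 ± 1.22 FPKM (adjusted p = 7.85e-04), MT1X from 7 ± 2.22 to 2.84 ± 0.75 FPKM (adjusted p = 0.0434) and MT1M from 3.64 ± 0.35 to 1.40 ± 0.60 FPKM (adjusted p = 0.0155). The activin subunit genes INHBB and INHBE fell by 0.88 and 0.95 on the log2 scale (-1.93 for the gene INHBE with a pseudocount of 0.1), ANGPT1, which encodes the vessel growth factor angiopoietin 1, fell by 0.91, and CMKLR1, the chemerin receptor, fell by 1.08.

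**Figure D1:**
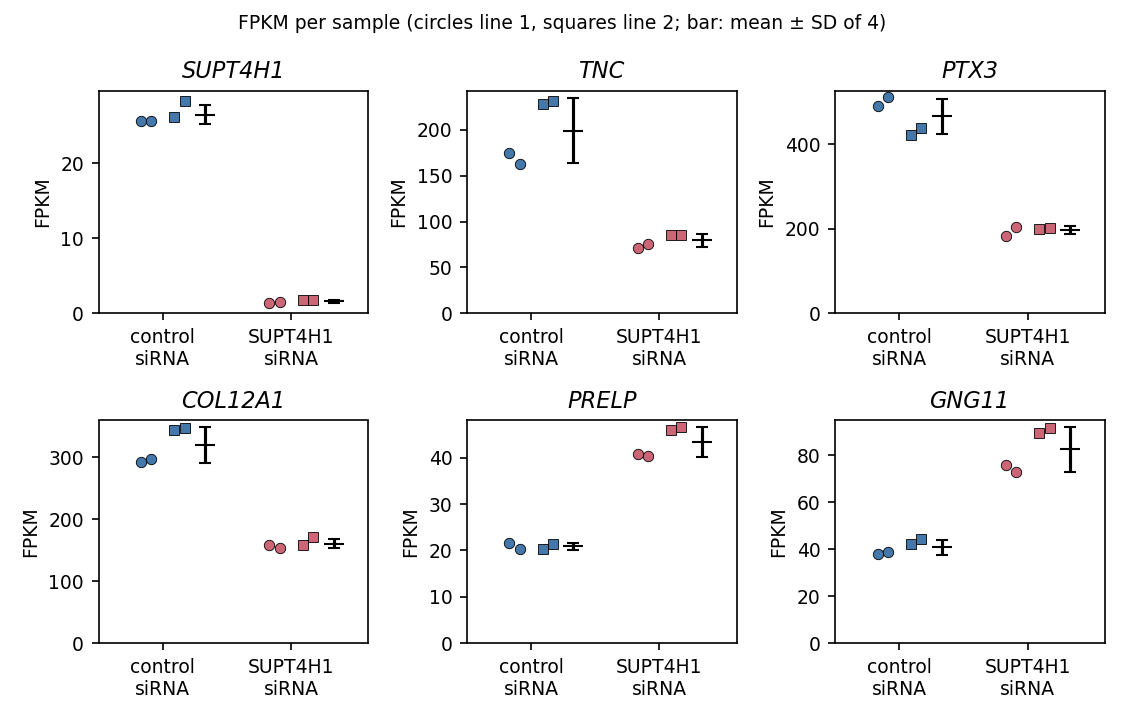
FPKM of SUPT4H1, TNC, PTX3, COL12A1, PRELP and GNG11 in each of the 8 samples, with circles for line 1 and squares for line 2 and a bar for the mean ± SD of the 4 samples of a group. In each panel the SUPT4H1 siRNA samples lie apart from the control samples, as for PTX3 with means of 465.9 and 197.4 FPKM.

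In all, 408 genes rose and 202 fell, with a median absolute log2 change of 0.306, and 6 of the rises and 6 of the falls reached 1 on the log2 scale. In each of these 610 genes, TNC and SERPINB2 among them, both SUPT4H1 siRNA samples of each line lay on the same side of both control samples of that line. As these genes were called on the same values, this ordering is no separate support for the calls. Over all genes 3291 were so ordered upwards and 1891 downwards, where chance gives 2.78% or 317.3 genes per direction. With the line as replicate block, 3073 genes rose and 1738 fell, and all of the 408 and 202 were among them. After scaling by median ratios the split was 245 up and 265 down, so that 48% of the calls were rises against 66.9% without it, and the counts depend on that choice. Leaving out any 1 of the 8 samples left 123 to 252 rises and 90 to 136 falls. Of the 58 named genes called besides SUPT4H1, 24 were called under every setting in which they were tested, the fits without 1 sample included: ACAT2, ANGPT1, CEMIP, CMKLR1, COL12A1, GNG11, IER3, IFI6, IFIT2, INHBE, LOC101927740, LTBP1, MT1E, PALMD, PLK2, PRELP, PTX3, SAMD9L, SDPR, TFPI2, TGFB1, TGFBR1, TM7SF2 and TNC. Some of these 24 were not tested under every setting, as a stricter filter on FPKM leaves out low genes such as TM7SF2. Each of the rest of the 58 lost its call under at least 1 setting.

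Extracellular matrix genes were lower after SUPT4H1 siRNA. Of the 52 collagens and extracellular matrix genes tested, 8 fell and 0 rose over all genes tested, 9 fell adjusted over the list alone, and the median log2 change was -0.24 with 42 members below 0 (camera adjusted p = 1.6e-08, and adjusted p = 0.0292 with an estimated correlation). The 8 were TNC, COL12A1, LTBP1, THBS1, MFAP5, P4HA1, COL5A3 and COL6A3. THBS1, the matrix glycoprotein thrombospondin 1, fell from 1438 ± 23.4 to 818.3 ± 17.6 FPKM (adjusted p = 0.00277), LTBP1, which binds latent TGF-beta in the matrix, from 40.5 ± 3.25 to 22.5 ± 0.99 FPKM (adjusted p = 0.00131), and COL6A3, a chain of type VI collagen, from 404.3 ± 26.2 to 291.4 ± 14 FPKM (adjusted p = 0.0126). VCAN, the proteoglycan versican, went the other way in value, with 39.5 ± 3.65 and 49.1 ± 6.72 FPKM, and did not pass (adjusted p = 0.159), although it did with the line as replicate block (adjusted p = 1.25e-04). With that block 32 members fell and 4 rose, and the list's adjusted p with an estimated correlation was then 0.301.

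The most abundant collagen genes could not be compared. COL1A1 is listed at 0 in all 4 control samples because of its status, and stood at 3884, 3996, 3382 and 3387 FPKM after SUPT4H1 siRNA. COL1A2 is listed at 0 in the control samples and in 1 SUPT4H1 siRNA sample, and FN1, the gene of fibronectin, in all samples but the 2 SUPT4H1 siRNA samples of line 1. No change can be given for these genes.

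Cytosolic ribosomal protein mRNAs were lower as a group, most by a small amount. Of 75 tested, 69 had a log2 change below 0 and 6 above it, with a median of -0.195 (camera adjusted p = 8.98e-14, and adjusted p = 0.421 with an estimated correlation). RPL23A alone passed over all genes tested, with a fall from 42.5 ± 3.89 to 33.1 ± 2.75 FPKM (adjusted p = 0.0494), and 0 passed adjusted over the list alone. The call of RPL23A was lost without any 1 of the 8 samples (adjusted p = 0.0651 to 0.13), with no filter on FPKM (0.0709), without the mean-variance trend (0.0531) and with the correction for GC content and length (0.0551). With all samples and the line as replicate block, RPL23A passed (adjusted p = 5.5e-05). RPS6, a protein of the small ribosomal subunit, stood at 877.2 ± 98.4 and 778.4 ± 117 FPKM and did not pass (adjusted p = 0.551, and 0.00651 with the line as replicate block). RPLP1, RPL10, RPL13A, RPL17, RPS12 and RPS19 had changes above 0, up to 0.10, and none of them passed. Under the replicate block by line 55 of the 75 fell and 0 rose.

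Of 39 genes of the integrated stress and unfolded protein response, 2 fell and 0 rose, also adjusted over the list alone. In this list 30 had a change below 0, with a median of -0.095 (camera adjusted p = 1.63e-04, and adjusted p = 0.316 with an estimated correlation). DDIT4, an inhibitor of mTORC1 signalling, fell from 78.3 ± 1.41 to 46.9 ± 10.1 FPKM (adjusted p = 0.0244) and DDIT3, the stress transcription factor CHOP, from 30.3 ± 1.10 to 22.0 ± 3.46 FPKM (adjusted p = 0.045). ATF4, the transcription factor that drives the response, stood at 219.4 ± 3.15 and 173.2 ± 24.8 FPKM and passed with the line as replicate block but not without a block (adjusted p = 0.0023 and 0.091). With that block 18 members fell and 3 rose.

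Among the 29 contractile and TGF-beta target genes tested, 3 fell and 0 rose, also adjusted over the list alone: TGFBR1, a TGF-beta receptor, fell from 18 ± 1.2 to 12 ± 0.88 FPKM (adjusted p = 0.00587), TGFB1, the cytokine itself, from 41.2 ± 0.40 to 31.1 ± 1.22 FPKM (adjusted p = 0.00254), and MYLK, myosin light chain kinase, from 46.3 ± 1.28 to 38.9 ± 1.26 FPKM (adjusted p = 0.0152). The list's test pointed down (camera adjusted p = 9.55e-04, and adjusted p = 0.611 with an estimated correlation) with a mean of -0.132, but the median was only -0.02, with 14 members above 0 and 15 below. The median was unstable. It was 0.08 or 0.067 without SUPT4H1 line 1 replicate 1 or 2 and 0.012 or 0.009 without control line 2 replicate 1 or 2. It was -0.166 or -0.185 without control line 1 replicate 1 or 2 and -0.194 or -0.201 without SUPT4H1 line 2 replicate 1 or 2. It was also above 0 with a stricter filter on FPKM (0.03) and with array weights (0.049). It was -0.008 with no filter, -0.055 after scaling and -0.034 with the correction for GC content and length. ACTA2, smooth muscle actin, stood at 110.2 ± 60.04 and 106.9 ± 54.7 FPKM and did not pass (adjusted p = 0.992). In the fit with the line as replicate block 12 members fell and 7 rose.

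Of 27 immediate early genes, which respond to growth factors and stress within minutes, 2 fell and 1 rose, and 3 fell and 2 rose adjusted over the list alone. Their median was -0.11 (camera adjusted p = 0.0191, and adjusted p = 0.316 with an estimated correlation). KLF2 fell from 7.53 ± 0.52 to 4.79 ± 0.75 FPKM (adjusted p = 0.0165) and IER3 from 17.4 ± 0.60 to 11.9 ± 1.28 FPKM (adjusted p = 0.00954), while KLF4 rose from 35.3 ± 1.98 to 43.1 ± 0.34 FPKM (adjusted p = 0.0155). The list's call was lost after scaling (adjusted p = 0.0642), with repeated symbols left out (0.0564), without control line 1 replicate 1 (0.0569, with a median of 0.028) and without SUPT4H1 line 1 replicate 2 (0.0547). The median was -0.055 with a stricter filter on FPKM, -0.032 without control line 1 replicate 2, -0.055 or -0.072 without SUPT4H1 line 2 replicate 1 or 2, and -0.216 or -0.168 without control line 2 replicate 1 or 2. Blocking by line gave 14 falls and 5 rises.

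Cholesterol synthesis genes were higher as a group. Of 26 tested, 24 had a change above 0 and 4 rose over all genes tested, 19 rose and 1, the cholesterol transporter NPC1, fell adjusted over the list alone, and the median was 0.22 (camera adjusted p = 1.6e-08, and adjusted p = 0.114 with an estimated correlation). TM7SF2, a sterol reductase, rose from 1.67 ± 0.11 to 3.38 ± 0.16 FPKM (adjusted p = 0.00103), ACAT2, which makes acetoacetyl-CoA, from 3.90 ± 0.08 to 5.59 ± 0.53 FPKM (adjusted p = 0.00953). FDPS, farnesyl diphosphate synthase, rose from 22.7 ± 0.92 to 27.3 ± 1.09 FPKM (adjusted p = 0.0222), and NSDHL, a sterol dehydrogenase, from 6.33 ± 0.17 to 7.65 ± 0.15 FPKM (adjusted p = 0.00996). Under the replicate block by line 22 members rose and NPC1 fell (adjusted p = 0.202 over all genes without the block and 0.043 with it).

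Of 28 heat shock protein genes tested, 5 rose and 0 fell, 8 rose adjusted over the list alone, and 26 had a change above 0 (median 0.13, camera adjusted p = 8.69e-05, and adjusted p = 0.0981 with an estimated correlation). HSPA1A, an inducible HSP70 whose reads a near-identical copy can share, rose from 12.4 ± 1.53 to 16.6 ± 0.61 FPKM (adjusted p = 0.0355), DNAJA1, a co-chaperone, from 48.7 ± 3.57 to 58.6 ± 1.90 FPKM (adjusted p = 0.0438), and HSPB8, a small heat shock protein, from 4.94 ± 0.20 to 6.18 ± 0.37 FPKM (adjusted p = 0.0233), with HSP90AA1 and DNAJB1 as the others. Of 29 p53 targets, 8 rose and 0 fell, 12 rose adjusted over the list alone, and the median was 0.168 (camera adjusted p = 1.24e-04, and adjusted p = 0.518 with an estimated correlation). This median was 0.095 without control line 2 replicate 1 and 0.107 without SUPT4H1 line 1 replicate 2, with the call kept. PLK2, a stress-responsive kinase, rose from 16.5 ± 0.76 to 26.2 ± 3.66 FPKM (adjusted p = 0.0118), BTG2, an antiproliferative gene, from 8.23 ± 1.38 to 12.8 ± 0.53 FPKM (adjusted p = 0.0204), and C12orf5, which encodes the fructose bisphosphatase TIGAR, from 3.33 ± 0.42 to 4.68 ± 0.34 FPKM (adjusted p = 0.0325). The best known p53 targets did not pass: CDKN1A, a cyclin-dependent kinase inhibitor, stood at 281.9 ± 0.63 and 283.5 ± 5.07 FPKM (adjusted p = 0.957) and MDM2, the ligase that degrades p53, at 18.7 ± 1.63 and 19.7 ± 1.89 FPKM (adjusted p = 0.707, and 0.0366 with the line as replicate block). With that block 19 heat shock genes rose and 1 fell, and 17 p53 targets rose and 0 fell.

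Of 34 interferon response genes tested, 5 rose and 0 fell, and 6 rose adjusted over the list alone. In value 28 had a change above 0 (median 0.174, camera adjusted p = 0.00574, and adjusted p = 0.421 with an estimated correlation). The median was 0.096 with no filter on FPKM, with the call kept. IFIT2, an antiviral protein, rose from 1.87 ± 0.24 to 3.94 ± 0.73 FPKM (adjusted p = 0.00998), IFI6, a mitochondrial protein induced by interferon, from 38.2 ± 1.79 to 52.7 ± 4.36 FPKM (adjusted p = 0.00979) and SAMD9L from 5.24 ± 0.48 to 7.14 ± 0.20 FPKM (adjusted p = 0.0125), with IFI44 and TRIM22 as the other calls. Blocking by line gave 19 rises and 3 falls.

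Mitotic cell cycle genes were all above 0 in log2 change, with a median of 0.245 over the 27 tested, but 0 passed on their own or adjusted over the list alone (camera adjusted p = 0.0267, and adjusted p = 0.804 with an estimated correlation). CKS2, a subunit of cyclin-dependent kinase complexes, stood at 8.61 ± 1.26 and 12.7 ± 2.11 FPKM (adjusted p = 0.0705, and 0.00194 with the line as replicate block), and PTTG1, the securin that holds sister chromatids together, at 4.21 ± 0.91 and 5.49 ± 1.56 FPKM (adjusted p = 0.445, and 9.87e-04 with it). With the block 15 of the 27 rose. The list was called neither without control line 1 replicate 1 (adjusted p = 0.201, median 0.163) or replicate 2 (0.172) nor without SUPT4H1 line 2 replicate 1 (0.428, median 0.131) or replicate 2 (0.41, median 0.125). Its median was 0.401 without SUPT4H1 line 1 replicate 2. Of 36 genes of DNA replication and S phase, RPA1, a subunit of the protein that binds single-stranded DNA, rose from 13.4 ± 0.83 to 15.8 ± 0.36 FPKM (adjusted p = 0.0395), 0 passed adjusted over the list alone, and the list did not pass (median 0.095, camera adjusted p = 0.102, and adjusted p = 0.611 with an estimated correlation). With the line as replicate block this list passed (adjusted p = 0.0403, and adjusted p = 0.666 with an estimated correlation and the block), with 14 rises and 1 fall.

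**Figure D2:**
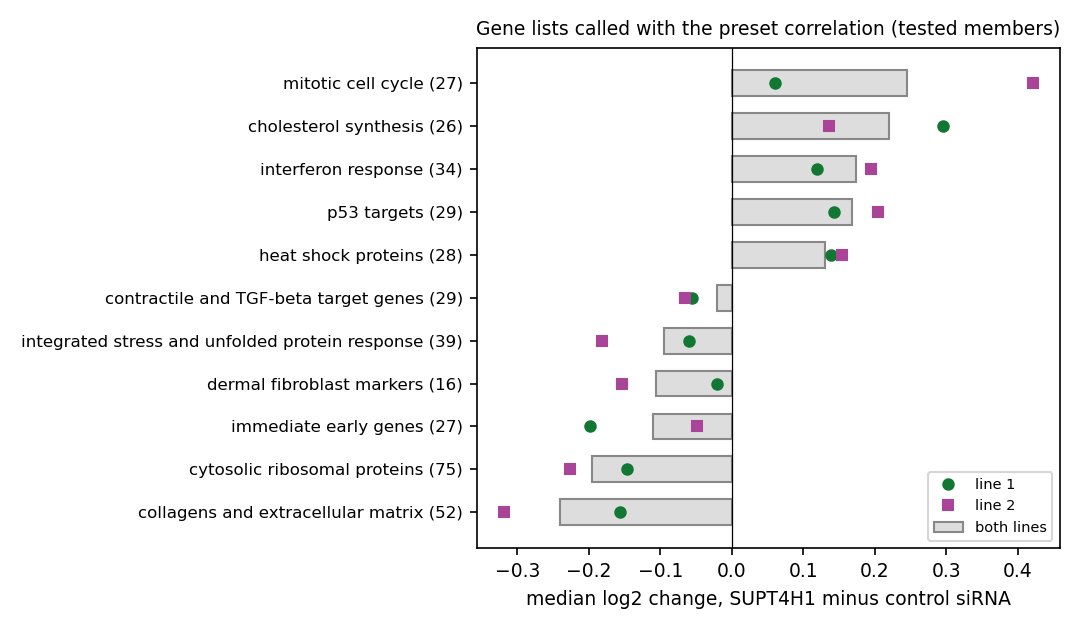
Median log2 change, SUPT4H1 siRNA minus control siRNA, of the gene lists that camera called with the preset correlation, with the number of tested members in brackets. Bars give both lines together, circles line 1 and squares line 2, from -0.24 for collagens and extracellular matrix to 0.245 for mitotic cell cycle genes. With an estimated correlation and no term for the line only the matrix list was called. With an estimated correlation and the line as replicate block no list was called.

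Among the factors that act with SUPT4H1, single genes passed in both directions. Of 39 transcription elongation factors, RTF1, a subunit of complexes that bind elongating polymerase, rose from 10.3 ± 0.08 to 11.8 ± 0.16 FPKM (adjusted p = 0.0163), MEPCE, which caps the 7SK RNA, rose from 12.9 ± 0.92 to 15.9 ± 1.02 FPKM (adjusted p = 0.0475), and TCEA2, a factor that rescues stalled polymerase, fell from 14.1 ± 0.61 to 11.9 ± 0.42 FPKM (adjusted p = 0.0282), beside the targeted gene. Adjusted over the list alone 4 rose and 2 fell, the median was 0.039 (camera adjusted p = 0.827, and adjusted p = 0.875 with an estimated correlation), and 7 rose and 5 fell with the line as replicate block. The list holds SUPT4H1 itself, whose fall makes the mean -0.061. Without it, an alternative added after the data were seen, the 38 others had a mean of 0.027 and a median of 0.041 and did not pass (adjusted p = 0.426, and 0.745 with an estimated correlation). Of 12 RNA polymerase II subunits, POLR2L rose from 109.0 ± 8.72 to 165.4 ± 21.8 FPKM (adjusted p = 0.022), 3 rose and 1 fell adjusted over the list alone, and the list did not pass (median 0.026, adjusted p = 0.766). With the block 3 of the 12 rose and 2 fell.

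Genes with disease-causing repeat expansions are of interest here because SPT4 is known from model systems to be needed for transcription through long repeats. Of 18 tested repeat expansion disease genes, 0 passed over all genes tested, where 610 of the 11423 genes passed, and 0 passed adjusted over the list alone (median 0.029, camera adjusted p = 0.766). HTT, the Huntington's disease gene, stood at 3.60 ± 0.04 and 3.85 ± 0.26 FPKM (adjusted p = 0.444). CSTB, an inhibitor of cathepsins, stood at 78.3 ± 23.4 and 88.7 ± 29.4 FPKM (adjusted p = 0.821, and 0.00179 with the line as replicate block), and CNBP, a nucleic acid-binding protein, at 54.3 ± 4.91 and 55.1 ± 6.97 FPKM (adjusted p = 0.959). With the block 6 of the list rose and 4 fell. C9orf72 lay below the filter, with 0.692 ± 0.064 and 0.696 ± 0.037 FPKM. These values are of whole genes and say nothing of expanded alleles.

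The remaining lists did not pass. Of 16 NF-kB and inflammatory genes, NFKBIZ, a nuclear regulator of NF-kB, fell from 4.12 ± 0.39 to 2.99 ± 0.16 FPKM (adjusted p = 0.0236), 2 fell adjusted over the list alone, and the list's adjusted p was 0.246, its test pointing down while the median was 0.008. Blocking by line gave 4 falls and 1 rise. Of 77 nuclear-encoded oxidative phosphorylation genes, NDUFC1, a subunit of complex I, SDHA, a subunit of succinate dehydrogenase, and CYCS, cytochrome c, rose by 0.24, 0.16 and 0.21 on the log2 scale, 0 passed adjusted over the list alone, and the list's adjusted p was 0.246. With the block 20 of these rose and 5 fell. Of 17 histone genes, H2AFX, the variant phosphorylated at DNA breaks, rose from 17.5 ± 0.88 to 20.5 ± 0.44 FPKM (adjusted p = 0.0318), also adjusted over the list alone, and the list's adjusted p was 0.246. With the block 8 of these rose and 2 fell. Of 45 mRNA decay and splicing factors 0 passed, alone or over all genes, and the list's adjusted p was 0.246. HNRNPA2B1, an RNA-binding protein, stood at 113.1 ± 11.9 and 125.9 ± 10.2 FPKM (adjusted p = 0.394, and 0.00102 with the block) and HNRNPK, another, at 88.1 ± 5.11 and 88.2 ± 7.2 FPKM. With the block 18 of these rose and 4 fell.

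Dermal fibroblast markers had a median below 0 that depended on single samples, and markers of other cell types stayed mostly below the filter. Of 16 fibroblast markers tested, MFAP5, a microfibril protein, fell from 31.9 ± 5.87 to 19.7 ± 0.55 FPKM (adjusted p = 0.024) and FAP, a membrane protease of activated fibroblasts, from 73.7 ± 3.26 to 59.3 ± 3.33 FPKM (adjusted p = 0.0215), also adjusted over the list alone. The median was -0.106 (camera adjusted p = 0.0114, and adjusted p = 0.421 with an estimated correlation), and the call was lost with genes of any status kept (adjusted p = 0.292). That setting adds COL1A1 and COL1A2, whose zeros in the control samples are failed estimates that read as rises. The median was -0.001 or -0.015 without control line 1 replicate 1 or 2 and 0.017 or -0.003 without SUPT4H1 line 2 replicate 1 or 2. It was -0.206 or -0.202 without control line 2 replicate 1 or 2 and -0.231 or -0.232 without SUPT4H1 line 1 replicate 1 or 2. Blocking by line gave 6 falls and 3 rises. Of the 16 keratinocyte markers 2 were tested, KRT10 and DSP, both structural proteins of epithelia, and neither passed (adjusted p = 0.623 and 0.949). KIT, the tested melanocyte marker, stood at 9.44 ± 2.22 and 6.99 ± 1.79 FPKM (adjusted p = 0.329, and 2.98e-05 with the block), EGFL7, the tested endothelial marker, at 3.60 ± 0.97 and 2.52 ± 0.79 FPKM (adjusted p = 0.334, and 4.67e-04 with it), and TUBB3, the tested neuronal marker, at 25.9 ± 9.29 and 23.5 ± 7.31 FPKM (adjusted p = 0.887, and 0.0386 with it). Of 3 immune markers, CD68, a lysosomal membrane protein of macrophages that other cells also make, rose from 46.2 ± 2.93 to 65.3 ± 10.0 FPKM (adjusted p = 0.0459). Of 3 markers of smooth muscle and pericytes, NOTCH3, a receptor, fell from 10.5 ± 0.34 to 8.90 ± 0.19 FPKM (adjusted p = 0.0173). With no filter on FPKM, where this list has enough members for camera, it pointed down (median -0.077, adjusted p = 0.0395).

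Analysed on its own, each line gave more calls, and the direction was largely shared. SERPINB2, TNC, PTX3 and COL12A1 passed in both lines. In line 1, 2171 genes rose and 1330 fell, and in line 2, 3084 rose and 1815 fell. Rises in both lines numbered 1564, where independent lists would share 586.1, and falls in both numbered 895, where they would share 211.3, while 53 rose in line 1 and fell in line 2 and 39 did the opposite. The lines share 1 estimate of spread per gene, so their lists are not independent and the overlaps are a description. The log2 changes of the lines correlated with Pearson's r = 0.675 across genes, which are not independent replicates. Without control line 1 replicate 1, the calls in line 1 went from 3501 to 2274.

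By the test of the difference, the response differed between the lines for 1126 genes, 614 with a higher and 512 with a lower change in line 2. The spread in this test is that between the 2 replicates of each siRNA in each line. If such replicates share a culture, a difference between the lines cannot be told from one between single transfections. SULF1, an enzyme that removes sulfates from heparan sulfate, went from 10.12 and 9.35 to 12.89 and 12.95 FPKM in line 1 and from 11.24 and 12.03 to 43.64 and 45.89 FPKM in line 2, a difference of 1.48 on the log2 scale (adjusted p = 3.91e-06). COL15A1, a basement membrane collagen, went from 229.75 and 226.47 to 182.49 and 183.12 FPKM in line 1 and from 36.04 and 34.19 to 8.09 and 8.60 FPKM in line 2, a difference of -1.63 (adjusted p = 4.04e-07). DCLK1, a microtubule-associated kinase, had log2 changes of 0.13 and 1.79 in lines 1 and 2, and CEMIP -1.63 and -0.87. MFAP4, a matrix protein, had log2 changes of -0.09 and -1.09, and ADRA2A, an adrenergic receptor, 0.18 and -0.70. OLFM2, a secreted olfactomedin protein, had 0.44 and -0.82. CHI3L1, a secreted chitinase-like protein, fell by 2.53 in line 1, while its level in line 2 was at most 0.13 FPKM, where a change on this scale must lie near 0. Over both lines together DCLK1, SULF1, CHI3L1, COL15A1 and MFAP4 did not pass without a block and passed with the line as replicate block (adjusted p = 0.0202, 0.00606, 0.0241, 0.00889 and 0.0193). With line and replicate number as block, SULF1 (0.0242) and COL15A1 (0.0317) passed, and DCLK1 (0.0556), CHI3L1 (0.0634) and MFAP4 (0.0535) did not.

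Of the 1126 genes, 657 changed in the same direction in value in both lines, 484 of them more in line 2 and 173 more in line 1, and 469 had opposite signs, of which 92 passed in both lines. Among the lists, mitotic genes had a median of 0.06 in line 1 and 0.422 in line 2 (camera adjusted p = 6.29e-12 for the difference), and matrix genes -0.156 and -0.319 (adjusted p = 2.64e-12). Cholesterol synthesis genes had a median of 0.295 in line 1 and 0.136 in line 2 (adjusted p = 3.47e-05). With an estimated correlation, run after the data were seen, none of these differences passed (adjusted p = 0.264 for each). The count of 1126 was 626 to 690 without control line 1 replicate 1 or 2, SUPT4H1 line 1 replicate 2 or SUPT4H1 line 2 replicate 1 or 2, and 730 with no filter on FPKM.

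**Figure D3:**
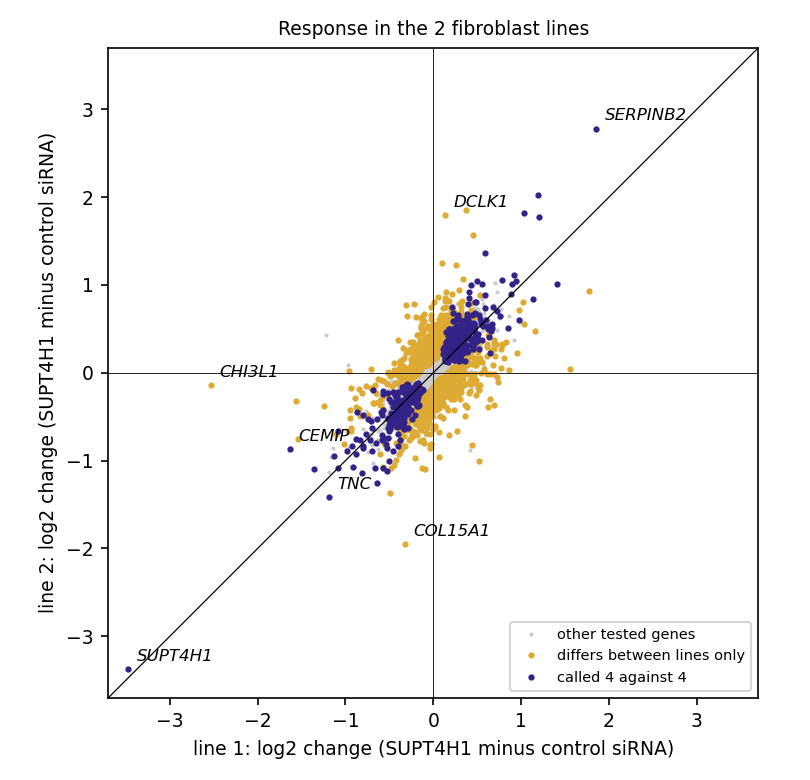
Log2 change, SUPT4H1 siRNA minus control siRNA, of each tested gene in line 1 (horizontal axis) and line 2 (vertical axis), with genes called 4 against 4 and genes that differ only between the lines in separate colours and a diagonal where both lines changed equally. Most genes called 4 against 4 lie near the diagonal, and COL15A1 (-0.32 and -1.95) and DCLK1 (0.13 and 1.79) lie far from it.

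Because DSIF acts on elongating polymerase, the change was also compared by the genomic span of the genes. The mean log2(FPKM + 1) of the 25% of genes with the longest span minus that of the 25% with the shortest was -0.537 ± 0.012 in the control samples and -0.559 ± 0.009 in the SUPT4H1 siRNA samples, a difference of -0.021 that did not pass an exact permutation test (p = 0.0571, with 0.0286 the smallest possible). In each line both SUPT4H1 siRNA samples lay below both control samples: -0.549 and -0.569 against -0.522 and -0.537 in line 1, and -0.554 and -0.563 against -0.539 and -0.551 in line 2. With the line as replicate block the exact permutation p was 0.0556, the smallest that the 36 arrangements within the lines allow, so that this test cannot pass the threshold. Median log2 changes were 0.032, 0.035, 0.039 and 0.012 from the shortest to the longest group of equal size, and the longest group held 88 rises and 89 falls against 93 and 47 in the shortest. The difference passed at p = 0.0286 in an exact permutation test for genes of at least 5 FPKM (-0.02), for spans over 100 kb against under 10 kb (-0.03) and without control line 2 replicate 2 (-0.026). It was -0.008 (exact permutation p = 0.343) with no filter on FPKM and -0.013 (exact permutation p = 0.343) after correction for GC content and transcript length, an alternative added after the data were seen.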

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

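The tests of the knockdown and of the depth in both lines and of the COL1A1 estimates were chosen only after their results were seen, as were the comparison with matched genes that keeps repeats, the estimated correlation for the line differences of the lists, the terminal oligopyrimidine mRNAs with members left out and the use of intervals for the knockdown. The members of the terminal oligopyrimidine list were also chosen after values of the data were seen. The other tests were written down beforehand.

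Among 160 groups of 4 samples, 4 held a sample far from the others by Dixon's ratio, where chance gives about 1 in 20. All were control samples: MT1M (ratio 0.92, FPKM 4.17, 3.44, 3.44 and 3.50), TCEA2 (0.86), IER3 (0.857) and DDIT4 (0.853). In MT1M the range was 3.44 to 4.17 FPKM, small beside the fall to 1.40 FPKM.

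The response differed between the lines, by the test of the difference, for 1126 genes. Differences in log2 change, line 2 minus line 1, were above 0 for SERPINB2 (0.93), LOC101927740 (0.84), SDPR (0.57), CLCA2 (0.78), PRELP (0.20), LRRC17 (0.78), CEMIP (0.77), PTX3 (0.26), PLK2 (0.44), BTG2 (0.38), IFIT2 (0.55), SAMD9L (0.23), MFAP5 (0.42), DSP (0.51), CD68 (0.53), DCLK1 (1.66), SULF1 (1.48) and CHI3L1 (2.39). They were below 0 for C1QTNF1 (-0.30), TNC (-0.23), INHBE (-0.61), TGFBR1 (-0.31), DDIT4 (-0.50), DDIT3 (-0.35), COL15A1 (-1.63), ADRA2A (-0.88), MFAP4 (-1.001) and OLFM2 (-1.25). For CEMIP, PTX3 and MFAP5 a value above 0 means a smaller fall in line 2. Among the lists, adjusted p-values for the difference were 0.0135 for immediate early genes, 0.00605 for interferon response genes, 2.64e-12 for collagens and extracellular matrix, 6.29e-12 for mitotic genes, 0.00564 for DNA replication genes, 3.47e-05 for cholesterol synthesis, 2.78e-07 for the integrated stress and unfolded protein response, 9.66e-04 for ribosomal proteins and 0.00564 for histone genes. With an estimated correlation none of these lists passed (adjusted p = 0.264 to 0.666).

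For the difference between the lines, lower depth in the libraries of 1 line is argued against, as the mean relative depth was 0.958 in line 1 and 0.941 in line 2, a ratio of 0.983, and the libraries overlap, at 0.82 to 1.03 and 0.863 to 1.127. A stronger knockdown in line 2, which has more response genes, goes against the direction of the values, as 6.21 and 6.39% of SUPT4H1 mRNA was left in its samples (mean 6.3%) against 5.34 and 5.58% in line 1. It is not excluded beyond error, since the intervals of the samples combined give a difference of 0.84 percentage points with bounds of -0.56 and 2.24, and the difference between the lines in SUPT4H1 did not pass in limma (log2 0.09, SE 0.06, adjusted p = 0.397). Differences between the donors of the lines, or between single cultures or transfections, stay open and untested. The design does not separate them from the lines.

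For the lower ribosomal protein mRNAs, a bias from GC content or transcript length was argued against, since the median was -0.201 after correction (camera adjusted p = 1.24e-10, and 1.44e-16 with the line as replicate block; without the correction, adjusted p = 0.421 with an estimated correlation, and 0.301 with the block). So was a compression of abundant transcripts, since genes matched in FPKM with repeats kept (median 256.6 FPKM against 261.7 for the list) had a median change of 0.018 (0.037 for the 421 counted once, a poor match at 96.3 FPKM). The ribosomal genes share a 5′ terminal oligopyrimidine motif with other mRNAs. A list of 16 such mRNAs other than ribosomal proteins, chosen after values were seen, had a median of -0.102. This passed the bound for a shared fall (-0.0975) by a narrow margin. The rule for that bound was set beforehand, while its value comes from the ribosomal median of these data. Over the 12 of the translation machinery, without VIM, HNRNPA1, NAP1L1 and TPT1, the median was -0.113. Of those left out, HNRNPA1 (0.12) and NAP1L1 (0.10) rose with the line as replicate block (adjusted p = 0.00266 and 0.0129). VIM (-0.09) and TPT1 (-0.21) had changes below 0. By line, the 16 had medians of -0.049 in line 1, short of that bound, and -0.151 in line 2. The ribosomal medians were -0.146 and -0.227. Of these 16, 0 passed on their own (2 rose and 10 fell with the line as replicate block). Camera gave the list an adjusted p of 0.00432, and 0.428 with an estimated correlation. As its members were chosen after values were seen, neither is an independent test. A shared control of these mRNAs may thus be part of the pattern, as a hypothesis found and tested on the same data.

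The lower matrix genes had a median of -0.256 after correction for GC content and length (camera adjusted p = 1.04e-06, and 5.32e-11 with the line as replicate block, while without the correction an estimated correlation gave adjusted p = 0.0292, and 0.301 with the block), and 393 genes matched in FPKM had a median of 0.02 (0.015 with repeats kept), which argues against both technical trends. A lower share of fibroblasts was asked through the markers of other cell types, and 55.6% of the 27 such markers above 0.1 FPKM were higher. KIT and EGFL7 were lower in value while CD68 rose. Smooth muscle and pericyte markers pointed down with no filter on FPKM (median -0.077, camera adjusted p = 0.0395). These values cannot decide on that share. The samples are fibroblast lines, most of these markers lay below the filter, and the values do not tell which cells made the mRNA. A fall of matrix mRNAs after loss of SUPT4H1 may be biological, as a hypothesis, and neither its cause nor any effect of the siRNA itself outside SUPT4H1 was tested, as the labels name 1 siRNA treatment against SUPT4H1.

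Of the 35 splits of the 8 samples into 4 and 4, 2 called as many genes as the real one, a share of 0.0571, so that chance cannot be excluded by this count. The other split is that between the lines, with 5645 calls against 610, which points to a structure of the samples, and the remaining splits called 0. Among the 18 splits that part both lines evenly, the real one called 610 genes against at most 0 in the others, and with the line as replicate block 4811 against at most 1, but a share under 0.05 cannot be had from 18 splits, the smallest being 0.0556.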

How the results depend on the processing

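The correction for GC content and transcript length, the line block together with an estimated correlation and the elongation factors without SUPT4H1 were chosen after the data were seen; the other settings were chosen beforehand. SUPT4H1 stayed past the threshold under every setting, at -4.01 to -3.39. Of the 58 named genes called besides it, 24 were called under every setting in which they were tested, TNC, PTX3, COL12A1, CEMIP, PRELP and GNG11 among them. Under the settings that keep all samples, 43 were called wherever they were tested. A gene that a setting leaves out has no value there. Of 1141 values 902 stayed past the threshold, 239 did not, and 0 turned in sign. Precision limits low genes most, as intervals at 1 to 2 FPKM are 14.75 to 17.41% of the value.

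siRNA genes up went from 408 to 3073 with the line as replicate block, 2593 with line and replicate number as replicate block, 245 after median ratio scaling and 2503 with the correction for GC content and length and the line as replicate block, and siRNA genes down from 202 to 1738, 1442 and 2213 under the blocks and that correction. The block removes the difference between the lines from the spread. Besides these counts and the calls of genes, lists and list members given with the block beside their results, it changed no other call of a gene named in the text or of a list. Without 1 sample, up counts were 123 to 252 and down counts 90 to 136. Line 1 response genes were 2274 to 3540 and line by siRNA interaction genes 626 to 873 without 1 sample (730 with no filter on FPKM), and line 2 response genes stayed within 3729 to 4904. With an estimated correlation, gene lists up went from 5 to 0 and gene lists down from 6 to 1. The long minus short genes value was -0.02 at FPKM of at least 5 and -0.03 for spans over 100 kb against under 10 kb, both past the threshold, and -0.026 to -0.016 without 1 sample. The cause was not tested for the scaling, filter and span settings or for the fits without 1 sample.

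A gene's sign or the direction of a list's test turned only where neither setting gave a call. With the test still pointing down, medians rose above 0 in some settings for contractile and TGF-beta target genes (-0.201 to 0.08 without 1 sample), immediate early genes (0.028) and dermal fibroblast markers (-0.232 to 0.017 without 1 sample). CNBP was -0.019 after scaling, -0.001 with array weights and -0.005 with the correction for GC content and length, with or without the block. The median of transcription elongation factors went with a turn of the test's direction at 0.021 with FPKM of at least 5, 0.039 with the line as replicate block and with line and replicate number as replicate block, 0.007 after scaling and -0.001 with the correction, with or without the block. RNA polymerase II subunits were -0.006 after scaling, and at FPKM of at least 5 repeat expansion disease genes were 0.074 and NF-kB and inflammatory genes 0.057. Without 1 sample, ranges were -0.041 to 0.039 for HNRNPK, -0.047 to 0.071 for CNBP, -0.191 to 0.416 for DSP, -0.705 to 0.326 for OLFM2, -0.288 to 0.044 for TUBB3, 0.022 to 0.056 for transcription elongation factors and -0.01 to 0.063 for repeat expansion disease genes; the cause was not tested. Among the lists fixed beforehand, matrix genes alone kept the call under each setting that changes 1 choice (medians -0.279 to -0.212), and lost it with the line block and an estimated correlation together (-0.24, adjusted p = 0.301), where no list was called. With an estimated correlation the medians stay, by construction, at 0.168 for p53 targets, -0.11 for immediate early genes, 0.174 for interferon response, 0.245 for mitotic cell cycle, 0.22 for cholesterol synthesis, -0.095 for the integrated stress and unfolded protein response, 0.13 for heat shock proteins, -0.195 for ribosomal proteins, -0.106 for dermal fibroblast markers and -0.02 for contractile and TGF-beta target genes, and each call is lost. Immediate early genes also lost the call after scaling (-0.139) and with several-row symbols left out (-0.082), and dermal fibroblast markers with genes of any status kept (-0.089). The latter setting brings the failed zeros of COL1A1 and COL1A2 into the fibroblast list, where they read as rises. Without 1 sample, medians were -0.216 to 0.028 for immediate early genes and 0.125 to 0.401 for mitotic genes. The list DNA replication and S phase was gained with no filter (0.1, adjusted p = 0.0103), under both replicate blocks (0.095, adjusted p = 0.0403 and 0.0315) and after scaling (0.069, adjusted p = 0.0427), with the correction and the block (0.063, adjusted p = 0.0376) and without either SUPT4H1 siRNA sample of line 1 (adjusted p = 0.0486 and 0.0162), and ranged from 0.061 to 0.139 without 1 sample. Histone genes (0.1) and smooth muscle and pericyte markers (-0.077, adjusted p = 0.0395, too few members to test with the filter) were gained with no filter, and nuclear-encoded oxidative phosphorylation genes without control line 2 replicate 2 (0.025 to 0.087 without 1 sample). For the other changes in this paragraph the cause was not tested.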

Other observations

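The gene lists of this part, and the tests on them, were chosen after values of the data were seen, as was the test on COL1A1. Of 44 lysosomal enzymes and membrane proteins tested, 7 rose and 0 fell, and 8 rose adjusted over the list alone. In value 38 had a change above 0, with a median log2 change of 0.115 in both lines together, 0.109 in line 1 and 0.131 in line 2. As the list was made after values were seen, no test of it as a group is given. GRN, the precursor of granulins that reaches lysosomes, rose from 214.1 to 286.8 FPKM (log2 change 0.42, adjusted p = 0.0306), SMPD1, acid sphingomyelinase, from 50.1 to 74.2 FPKM (0.56, adjusted p = 0.00954), and IDS, iduronate sulfatase, from 33.8 to 46.3 FPKM (0.44, adjusted p = 0.0014). GLA, FUCA1 and CTSA, also lysosomal hydrolases, rose by 0.28, 0.45 and 0.31. With the line as replicate block 23 members rose and 2 fell.

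Of 5 metallothioneins tested, small proteins that bind zinc and copper, MT1E, MT1X and MT1M fell. This list was made because these 3 were among the largest falls, so no test of it as a group is given. MT2A had a change of -0.28 (adjusted p = 0.517, and 0.0194 with the line as replicate block) and MT1L of 0.21, which did not pass. Their sequences are alike, and reads shared among the members were not tested. Mitochondrial ribosomal proteins, 75 tested, had a median of 0.025 and 0 calls over all genes tested, with 10 rises and 5 falls with the line as replicate block.

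COL1A1 is listed at 0 in each control sample and has an estimate in each SUPT4H1 siRNA sample. A candidate explanation is that the control libraries held more COL1A1 fragments than the quantification accepts for a gene. The largest fragment number that the intervals imply for any gene with an estimate in a control library was 437173, for COL6A1, below the 570158 implied for COL1A1 in the SUPT4H1 siRNA library with the fewest. This leaves the explanation open, since genes above a limit have no estimate by construction and COL1A2 had an estimate with 811884 fragments in 1 SUPT4H1 siRNA library. The numbers also take each interval as counting error alone and may be too low for some genes. In SUPT4H1 line 1 replicate 1, THBS1 at 831.2 FPKM ranks among the largest numbers, and FN1 at 2307.58 FPKM does not. Were the explanation true with a limit of at least 811884, the controls would lie above 3693 to 4823 FPKM, 1.009 to 1.425 times the SUPT4H1 siRNA mean of the same line.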
